A study of Mus musculus with 12 samples.

How the data were processed

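RNA from whole hearts of male FVB/N mice, an inbred laboratory strain, was measured on 1-colour CodeLink mouse whole genome microarrays, 12 arrays in all. Per the labels and the series' own description, 6 mice were wild type and 6 were transgenic for human PLN, the gene of phospholamban, and all were 11 weeks old. The labels name no promoter, no copy number and no form of the transgene. RNA was extracted with Trizol from frozen tissue and turned into biotin-labelled cRNA, per the labels' protocols. The labels number the samples of a group 1 to 6, as many as the mice described, without stating outright that each came from a separate animal. Each is called a heart here, and the p-values measure only the spread between these samples, which may be technical.

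Each scanner file was written by CodeLink Expression Analysis software, version 4.2.0.18179, per the file headers. The deposited intensity columns hold the mean brightness of a spot, the median brightness of its local background, their difference, and that difference divided by the array's median over gene probes. The last 2 of these steps were tested on the values and are not described in a header. The deposited signal score sets a spot's brightness against local noise, and the software's near-background mark goes with scores of 1 or less. The authors' value table, also in intensity units, equals the scanner files' normalized column with a largest difference of 0 on every array. Its column medians run from 1.02 to 1.03, so its scale is known, and neither a log nor a centring of genes was applied. Other steps of the authors are not given in the sources used here.

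Each array holds 36227 spots, of which 34967 are gene probes. Between 2979 (8.52%) and 11184 (32.0%) gene probes per array were near background. The median of the background-subtracted intensity ran from 69.8 to 99.2 per array over a median local background of 59 to 64. Between 63 and 87 gene probes per array were saturated. The number of arrays limits the precision of every value.

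Background was corrected from the spot mean and background median with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50. Spots the software marked as masked, contaminated or irregular, and spots with a further mark that the files do not explain, were set to missing, and saturated spots were kept. Control spots were then left out, arrays were quantile normalized, and values were put on the log2 scale. A probe was kept if it was not near background on at least 6 of the 12 arrays and had at least 2 values per group, which left 28737 probes. Of these, 2003 had a missing value. Groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05. Differences are transgenic minus wild type. A probe saturated on every array of both groups is given no fold.

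Gene names came from the platform's annotation table, updated through gene IDs with the GRCm38.p6 gene table, then from the scanner files. One gene was named for 21615 probes from the former and for 7389 from the latter. Another 681 probes matched several genes and were left unnamed, as were 5282 with none. Of 29303 gene IDs given, 27589 were found in the GRCm38.p6 table. Because the files name no genome build, no coordinates are given, and the table served only for names and for the order of neighbouring genes. Different probes of a gene were tested separately. Where they disagree, each is given. The scanner files mark some named probes as having multiple targets, so that their differences may not be of the named gene alone. These are the first Myh7 probe, the Stat3 probe at -0.68 and the called probes of Rmnd1, Grk5 and Mybpc2.

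The 33 gene lists, on cardiac pathways and on cell types a heart sample can hold, were fixed before the data were examined, as were the main settings, the alternatives and the rule for named genes. Each list was tested with camera at its preset correlation of 0.01, over 17792 genes, each at its brightest probe. Missing values were filled with the group mean for these tests only. Benjamini-Hochberg adjustment ran over the 33 lists, each with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance one way and its mixed form whether they move at all. The difference in spread between hearts was tested with an exact permutation test over the distinct splits of the arrays into 6 and 6. The rule for named genes took every Pln probe and, among called probes with non-overlapping groups and a gene symbol other than a clone name, the 12 with the highest and the 12 with the lowest difference. It also took up to 4 called members per list, up to 2 members with the widest differences from lists without one, and 10 textbook genes of hypertrophy and calcium cycling.

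Alternatives covered the background correction, the normalization, the authors' value table with values under 0.01 set to 0.01, the filter on dim probes and the marked spots. Others covered the variance model, array weights, the threshold, a test without moderation, and each array left out in turn. Blocks for the replicate number and for the slide were also fitted. Slides were divided into the lower and the upper 6 serial numbers, each with 3 arrays per group, and the labels give all 12 arrays 1 date. The labels number both groups 1 to 6 without saying that a number is shared by a pair of mice. Leaving out pairs of arrays that stood apart, leaving out probes saturated on all 12 arrays from the list tests, where a gene then took its next brightest probe if it had one, and an exact permutation test of list means, were added after seeing the data. On data simulated from the means and spreads of 26734 probes, the comparison of transgenic with wild-type arrays called 66% of probes changed by 0.5 and 97% of those changed by 1 on the log2 scale. Of its calls there, 3.55% were of unchanged probes. The simulated noise was normal and independent between probes, so these rates need not hold for the real arrays.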

Results

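Whole hearts of 6 transgenic mice carrying human PLN and 6 wild-type mice of the same strain, sex and age were compared on 12 arrays, 6 per group. PLN encodes phospholamban, a small membrane protein of the sarcoplasmic reticulum that inhibits the calcium pump SERCA2a. The design asks which cardiac transcripts differ when the human gene is carried in the mouse heart. Any pair of arrays correlated at 0.977 to 0.994 across probes, and no pair held identical values. Wild-type heart 6 correlated at 0.989 to 0.991 with transgenic hearts 1, 2, 3 and 5, and at 0.980 and 0.983 with transgenic hearts 4 and 6. With the other wild-type hearts it correlated at 0.980 to 0.988. Between 8.52% and 32.0% of the gene probes on an array were near background, on average 23.0% in wild-type and 18.0% in transgenic hearts. The first principal component, with 22.1% of the variance, placed the transgenic arrays on the other side of 0 from every wild-type array except that of heart 5. The second, with 20.7%, set wild-type hearts 1 and 5 apart.

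The transgene's own level could not be read. The 1 mouse Pln probe was saturated on all 12 arrays, with a background-subtracted intensity of 36582 ± 1697 in wild-type and 35159 ± 2338 in transgenic hearts (SD, n = 6 each). It therefore checks neither the labels nor the dose of the gene. The main probe of Atp2a2, the gene of SERCA2, was also saturated on every array. A second Atp2a2 probe, made to an expressed sequence tag, was lower in transgenic hearts, at 10.95 ± 0.25 against 11.75 ± 0.16 log2 intensity (SD, n = 6 each), a log2 difference of -0.80 ± 0.11 (SE) with a limma adjusted p of 0.0021.

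Several genes classically raised in cardiac hypertrophy were higher in the transgenic hearts. Myh7, the slow beta-myosin heavy chain that the adult mouse ventricle normally keeps low, was 4.11-fold higher, at 11.22 ± 0.55 against 9.18 ± 0.36 log2 intensity (SD, n = 6 each, limma adjusted p = 1.67e-04). The scanner files mark this probe as having multiple targets, so its fold may not be of Myh7 alone. A second Myh7 probe, marked as having a single target, was 1.95-fold higher (limma adjusted p = 0.018), with overlapping groups, and 7 of 31 alternatives ended its call. Nppa, which encodes atrial natriuretic peptide, was measured 3.62-fold higher, at a limma adjusted p of 0.012, with 2 of its transgenic spots saturated, so that this fold is a lower limit. It missed the threshold in 6 of 31 alternatives. Acta1, the skeletal alpha-actin, was measured 1.87-fold higher with a log2 difference of 0.91 ± 0.10 (SE) and 1 transgenic spot saturated, likewise a lower limit. Ccn2, a matricellular growth factor, was 1.92-fold higher at a limma adjusted p of 0.047, and 20 of 31 alternatives ended its call. For Nppa, Acta1 and Ccn2 as for the first Myh7 probe, every transgenic heart lay above every wild-type heart. Nppb, the gene of brain natriuretic peptide, had a log2 difference of 0.65 ± 0.23 (SE) and missed the threshold at a limma adjusted p of 0.20, with wild-type heart 6 at 14.49 against 13.03 to 13.37 in the other wild-type hearts. Without that heart Nppb passed, at 0.86 with a limma adjusted p of 0.023, while over the alternatives that kept all hearts or left out pairs the adjusted p was 0.098 to 0.46. Myh6, the adult alpha-myosin heavy chain, differed by 0.22 ± 0.25 (SE), was not called and took either sign among the alternatives. Its probe read 8.97 ± 0.55 log2 intensity in wild-type hearts (SD, n = 6), below the 9.18 of the first Myh7 probe. The Myh6 probe is thus a doubtful measure of its gene, and an unchanged level cannot be read from it.

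**Figure D1:**
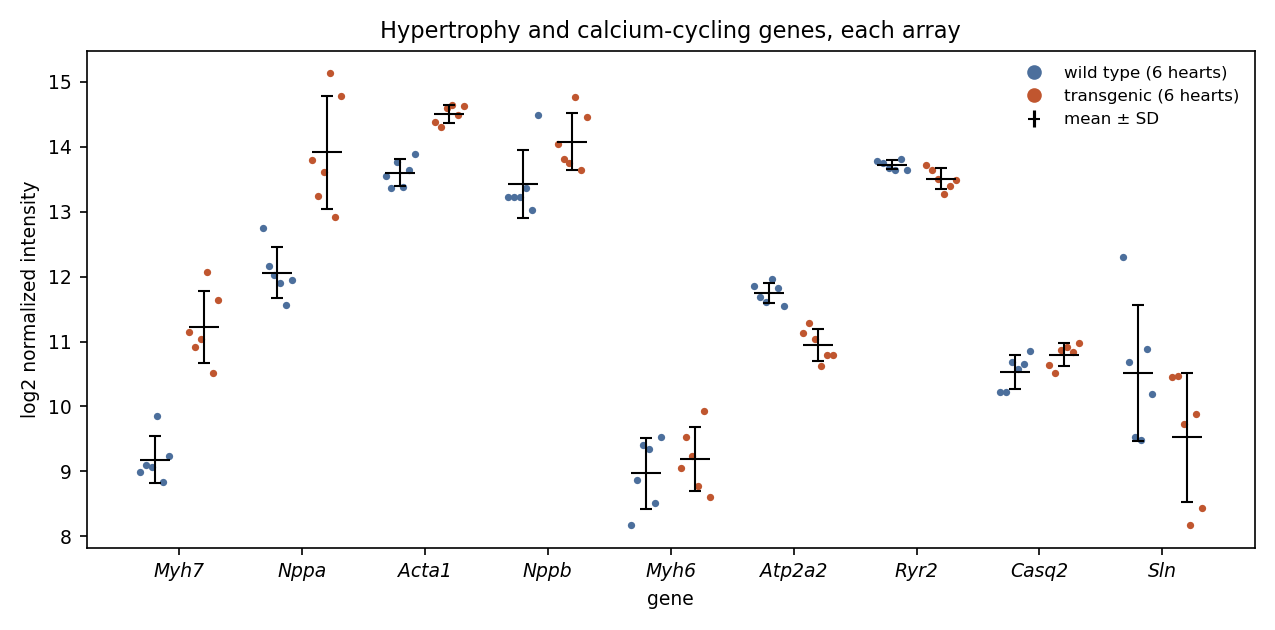
Log2 normalized intensity of 9 hypertrophy and calcium-cycling genes on each array, with points for the 6 wild-type and 6 transgenic hearts and bars for the mean ± SD. Myh7, Nppa and Acta1 lie higher and the unsaturated Atp2a2 probe lies lower in every transgenic heart, while the groups overlap for Nppb, Myh6, Ryr2, Casq2 and Sln.

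Over all 28737 probes, 130 differed between the groups, 79 higher and 51 lower in transgenic hearts (limma, Benjamini-Hochberg adjusted p under 0.05). They carried 108 gene symbols. At an unadjusted p under 0.05 there were 4280 probes, where 1437 would be reached by chance. The called differences were mostly small, with a median size of 0.57 on the log2 scale, and 16 probes changed at least 2-fold. The groups did not overlap for 108 of the 130. Over all probes the groups were separate for 1.56%, where chance gives 0.216%. The count changed when 1 heart was left out. It rose to 420 without wild-type heart 6. It fell to 75, 78, 61, 66 and 109 without wild-type hearts 1 to 5 in turn. Without transgenic hearts 1 to 6 in turn it was 84, 107, 76, 86, 91 and 69. Fewer arrays leave less power, so a fall by itself does not single out a heart. Each of the 130 kept its direction in every alternative that tested it.

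The 9 probes with the smallest adjusted p were all higher in transgenic hearts and included none of the 10 textbook genes. Single probes for Asnsd1 (5.98-fold), the sodium channel gene Scn8a (4.82-fold), Ankrd33b (3.21-fold), Mta3 (2.69-fold), the tRNA methyltransferase gene Trmt13 (2.55-fold) and the olfactory receptor gene Olfr798 (2.43-fold) were higher in all 6 transgenic hearts. Their limma adjusted p-values ran from 8.42e-10 to 5.97e-07. Other probes for 4 of these genes did not follow. The other Asnsd1 probe differed by -0.09, and 3 further probes each for Scn8a, Ankrd33b and Mta3 differed by -0.23 to 0.26 on the log2 scale, none of them called. On the raised probes, wild-type heart 6 lay near the other wild-type hearts. Its raised Asnsd1 probe read 10.765, against 10.823 to 11.218 in the other wild-type and 13.258 to 13.916 in the transgenic hearts. These probes were picked by their difference between the labelled groups. Also among the 12 highest by the naming rule were Pamr1 (2.05-fold), the cartilage intermediate layer protein gene Cilp (2.01-fold) and the phosphodiesterase gene Pde7b (1.92-fold). For Pde7b a second probe passed as well, at 0.55, and another differed by -0.12.

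**Figure D2:**
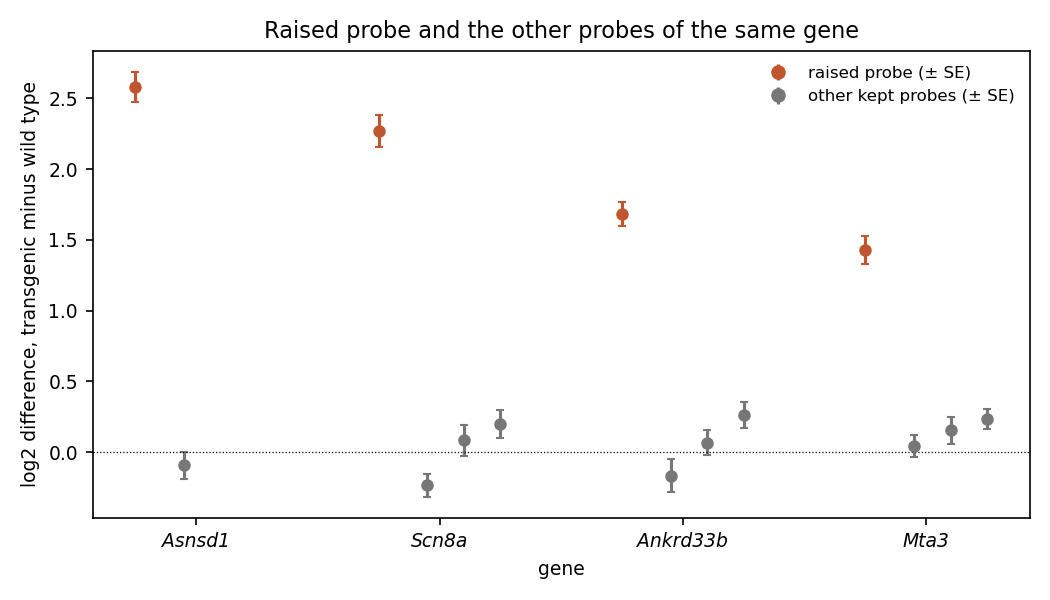
Log2 difference, transgenic minus wild type, with its standard error for the raised probe and for every other kept probe of 4 genes (12 arrays). The raised probes lie between 1.43 and 2.58 and the other probes between -0.23 and 0.26.

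Among the lower transcripts, the Ano10 probe, for a membrane protein of the anoctamin family, fell by 1.49 on the log2 scale (SE 0.13, limma adjusted p = 7.22e-06). Mylk4, a myosin light chain kinase, had a difference of -0.83, and Acot3, a peroxisomal acyl-CoA thioesterase, one of -0.77. Bdh1, which interconverts the ketone bodies acetoacetate and beta-hydroxybutyrate, had -0.64 and Myl1, a skeletal-type myosin light chain, had -0.55. Stat3, a transcription factor activated by cytokines, was lower on 2 probes, at -0.68 and -0.63, while another Stat3 probe differed by -0.11 and was not called. Rmnd1 (-0.84), Tlcd4 (-0.75), Adam23 (-0.57), Myo5c (-0.57) and Mfsd4a (-0.56) completed the lowest 12 with the Atp2a2 probe. A second Adam23 probe differed by -0.32 and was not called. Ano10, Mylk4, Acot3, Tlcd4 and the Atp2a2 probe stayed past the threshold in all alternatives. The sizes for 2 dim probes moved with the settings, from -1.18 to -0.39 for Acot3 and from -1.25 to -0.35 for Tlcd4. Of 31 alternatives, 22 ended the call of the Stat3 probe at -0.68, 17 that of Rmnd1 and 15 that of Myo5c. The call of Cilp was ended by 23, that of the first Pde7b probe by 15 and that of Pamr1 by 6. For the Stat3 probe at -0.63 and the second Pde7b probe, lost calls were not counted.

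As a group, the hypertrophy and fetal gene list was higher. Of its 28 measured genes 21 had a positive difference, with a median of 0.38 (camera adjusted p = 2.04e-05), but the adjusted p was 0.17 with an estimated correlation. Adjusted over all probes, 4 members were higher (Myh7, Nppa, Ccn2 and Acta1) and 1, Myl1, was lower. Adjusted over the list alone, 15 were higher and 2 lower. The second lower one, Myl7, an atrial myosin light chain, differed by -1.21. Fry gave an adjusted p of 0.019 for this list, and the exact permutation test of list means, added after seeing the data, gave 0.036. The list deviations of transgenic hearts 4 and 6 were 0.49 and 0.30 against 0.06 to 0.12 in the other transgenic hearts. Without these 2 hearts, an omission chosen after seeing the data, the median was 0.28 and the call was kept (adjusted p = 8.76e-06). The sarcomere list had a median of 0.07 over 30 genes (camera adjusted p = 0.0099, and adjusted p = 0.17 with an estimated correlation). The probes of 7 members were saturated on all 12 arrays. Without such probes, an omission added after seeing the data, the median was 0.13 over 24 genes and the call was kept (adjusted p = 0.0079). Its 1 called member was Myom2, an M-band protein gene, 1.89-fold higher, whose call 15 of 31 alternatives ended. In this list 2 members were higher adjusted over the list alone. Median scaling ended the sarcomere call, at an adjusted p of 0.066, in a range of 5.77e-04 to 0.19 over the alternatives that kept all hearts or left out pairs. In the skeletal muscle list, which was not called (camera adjusted p = 0.24), Acta1 and Mybpc2, a fast-type myosin-binding protein C (1.46-fold), were higher.

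Extracellular matrix genes were mostly higher, most so in 2 transgenic hearts. Of 49 measured genes 44 had a positive difference, with a median of 0.25 (camera adjusted p = 4.33e-06). The adjusted p was 0.47 with an estimated correlation, 0.11 by fry and 0.086 by the exact permutation of list means, so that none of these 3 tests called the list. None passed over all probes, and 4 were higher adjusted over the list alone. The widest differences were those of Tgfb2, a transforming growth factor, at 0.64 (limma adjusted p = 0.12), and of the proteoglycan gene Bgn at 0.51 (limma adjusted p = 0.11). Fibroblast markers had a median of 0.13 over 15 genes (camera adjusted p = 0.0145, and adjusted p = 0.64 with an estimated correlation), with 1 member, Col1a2, higher adjusted over the list alone and none over all probes. Without wild-type heart 3 or transgenic heart 4 the fibroblast call ended, at adjusted p-values of up to 0.065. Col1a1, Col1a2, Col3a1, Lum and Mfap5 stand on both lists. The 2 transgenic hearts with the highest matrix values were 4 and 6, whose mean log2 deviations over the list were 0.38 and 0.23 against -0.07 to 0.06 in the other transgenic hearts. Without both, an omission chosen after seeing the data, the matrix median was 0.08 and the call was kept (adjusted p = 0.0059), and without heart 4 alone the median was 0.17. Adipocyte markers had a median of 0.16 over 11 genes (camera adjusted p = 0.0017, and adjusted p = 0.17 with an estimated correlation), with Adipoq at 0.54 and Retn at 0.52. None of these passed over all probes, and 3 were higher adjusted over the list alone.

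**Figure D3:**
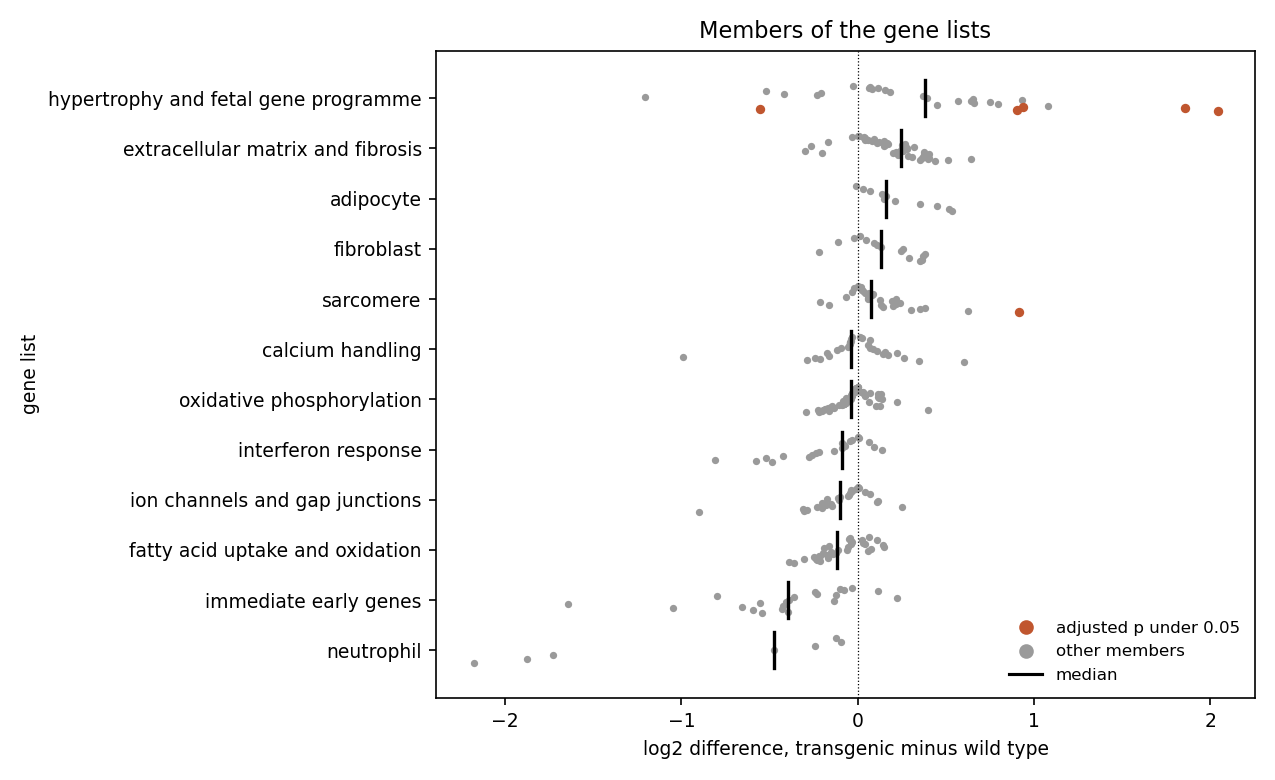
Log2 difference, transgenic minus wild type, of each measured member of the 11 lists called by camera and of the calcium handling list, with black bars at the list medians and coloured points for members with an adjusted p under 0.05. List medians run from -0.47 for neutrophil markers to 0.38 for the hypertrophy and fetal genes.

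Fatty acid and oxidative phosphorylation genes were lower by small amounts. Fatty acid uptake and oxidation had a median of -0.12 over 34 genes (camera adjusted p = 0.0145, and adjusted p = 0.68 with an estimated correlation), with Mlycd at -0.39 and Ech1 at -0.36. Oxidative phosphorylation had a median of -0.04 over 65 genes (camera adjusted p = 0.0145, and adjusted p = 0.51 with an estimated correlation), with Uqcrq at 0.40 and Ndufs4 at -0.29. The probes of 5 fatty acid and 16 oxidative phosphorylation members were saturated on all 12 arrays, which leaves little of a difference to read. Without such probes both calls were kept, with medians of -0.13 over 32 and -0.05 over 52 genes (adjusted p = 0.0146 and 0.0079). No member of either list passed, over all probes or adjusted over the list alone. These shifts went with single arrays. Transgenic hearts 4 and 6 had fatty acid list deviations of -0.39 and -0.23, and without these 2 hearts, an omission chosen after seeing the data, the list median was 0.02. The camera adjusted p was then 0.85, and it ran from 0.0036 over the alternatives that kept all hearts or left out pairs. The fatty acid call also ended without wild-type heart 1 or 6 or transgenic heart 4 or 6 alone (adjusted p = 0.074, 0.17, 0.22 and 0.14). The oxidative phosphorylation call ended without wild-type heart 6 or transgenic heart 4 or 6 (adjusted p = 0.056, 0.065 and 0.094). Ion channel and gap junction genes had a median of -0.10 over 27 genes (camera adjusted p = 0.021, and adjusted p = 0.17 with an estimated correlation), led by the sodium channel subunit gene Scn4b at -0.90 and by Abcc9 at -0.31, and no member passed either adjustment. Its call ended without transgenic heart 6 (adjusted p = 0.081).

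Immediate early, neutrophil and interferon-response genes were lower. Immediate early genes, which respond within minutes to stimulation, had a median of -0.39 over 22 genes (camera adjusted p = 9.05e-06, and adjusted p = 0.52 with an estimated correlation), with Egr2 at -1.64 and Nr4a1 at -1.05. None passed over all probes and 9 were lower adjusted over the list alone. Neutrophil markers had a median of -0.47 over 7 genes (camera adjusted p = 2.39e-04, and adjusted p = 0.27 with an estimated correlation), with S100a9 at -2.18 and S100a8 at -1.88. None passed over all probes and 4 were lower adjusted over the list alone. The neutrophil list deviations were -0.27 or higher in every wild-type heart and -0.39 or lower in every transgenic heart. Wild-type hearts 3 and 4 held the highest values of both lists, with S100a9 at 10.96 and 11.80 against 7.93 to 9.06 in the other wild-type and 6.71 to 7.56 in the transgenic hearts. Without these 2 hearts, an omission chosen after seeing the data, the immediate early list lost its call (median -0.08, adjusted p = 0.094), and the neutrophil list kept it (median -0.24, adjusted p = 1.61e-04). Interferon-response genes had a median of -0.09 over 21 genes (camera adjusted p = 0.0029, and adjusted p = 0.64 with an estimated correlation), with Iigp1 at -0.81 and Irf1 at -0.58. None passed over all probes, and 2 were lower adjusted over the list alone. Heat shock genes were not called (camera adjusted p = 0.24). Hspa1b, an inducible chaperone gene, had log2 values of 12.76 to 13.92 in wild-type hearts 1 to 5, 9.30 in wild-type heart 6 and 10.03 to 11.51 in the transgenic hearts. Without wild-type heart 6 the heat shock list was called, at an adjusted p of 0.0072.

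**Figure D4:**
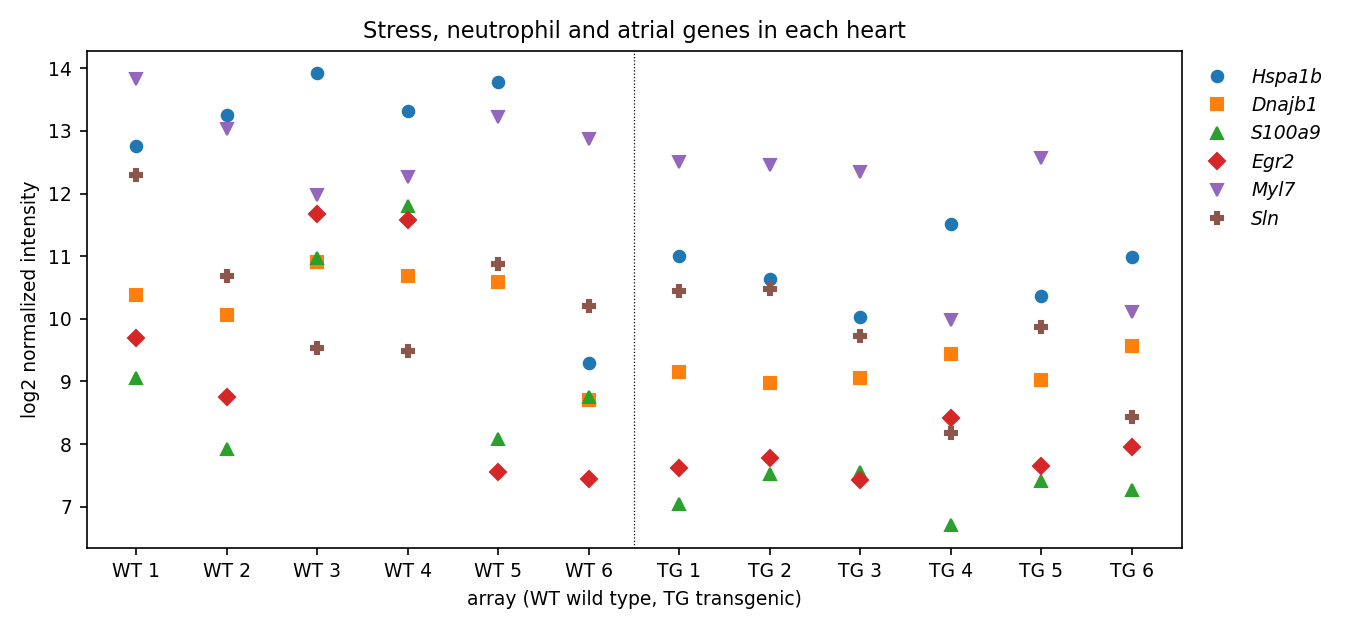
Log2 normalized intensity of 6 genes on each of the 12 arrays, 1 symbol per gene. Hspa1b and Dnajb1 are high in wild-type hearts 1 to 5 and low in wild-type heart 6, S100a9 and Egr2 peak in wild-type hearts 3 and 4, and the atrial genes Myl7 and Sln are lowest in transgenic hearts 4 and 6.

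The calcium handling list itself passed no test of a shift. With each gene at its brightest probe, none of its 31 measured genes passed over all probes, although the unsaturated Atp2a2 probe did, at -0.80. In the list 1 gene, Casq1 at 0.60, was higher adjusted over the list alone, and the median difference was -0.04 (camera adjusted p = 0.79). Sln, which encodes the SERCA inhibitor sarcolipin, differed by -0.99 ± 0.47 (SE), with SDs of 1.04 and 0.99 between hearts of a group, and by -2.27 and 0.28 within the first and second sets of slides. The ryanodine receptor gene Ryr2 differed by -0.22 and -0.13 on its 2 probes and the calsequestrin gene Casq2 by 0.26. The sodium-calcium exchanger gene Slc8a1 differed by -0.03 and 0.07, and none of these 4 genes was called. Fry's mixed form, which asks for change in either direction, gave an adjusted p of 0.0033, in a test that called 15 of the 33 lists. Pln itself and the brightest Atp2a2 probe, both saturated, enter this list without information. Without probes saturated on all 12 arrays, an omission added after seeing the data, the list held 30 genes with a median of -0.04 and was not called (adjusted p = 0.51). Among beta-adrenergic signalling genes, Grk5, a kinase that desensitizes adrenergic receptors, was 1.54-fold higher (limma adjusted p = 0.049) and was the 1 called member of 29 measured, over all probes and adjusted over the list alone (camera adjusted p = 0.53). A second Grk5 probe differed by 0.02, and 21 of 31 alternatives ended the Grk5 call.

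The other 22 lists were not called with the chosen settings. Their lowest camera adjusted p was 0.064, for the tricarboxylic acid cycle with a median of -0.09, followed by 0.067 for endothelial markers with a median of -0.13. With all hearts kept, the tricarboxylic acid cycle list was called with an offset of 200 and with the authors' table (adjusted p down to 0.012), and the endothelial list with an offset of 200 and with the mean over probes (adjusted p down to 0.043). The tricarboxylic acid cycle list was also called without wild-type heart 2 or 3 or transgenic heart 1, 2 or 3 (adjusted p = 0.0067, 0.043, 0.033, 0.049 and 0.033). The endothelial list was also called without wild-type heart 2 or 3 (adjusted p = 0.037 and 0.048). Macrophage markers had a median of -0.05 (camera adjusted p = 0.15) and were called without wild-type heart 6 or transgenic heart 4 or 6 (adjusted p = 0.030, 0.048 and 0.047). Without transgenic hearts 4 and 6 together their camera adjusted p was 0.0023. Without wild-type hearts 3 and 4, the endoplasmic reticulum stress and nerve lists were called, each at a camera adjusted p of 0.038. These omissions of pairs were chosen after seeing the data. Smooth muscle markers had a median of -0.04. Clu, on the mesothelial list, was 1.40-fold higher and was the 1 called member of that list, a call that 20 of 30 alternatives ended. Atrial markers had a median of -0.05 and a mean of 0.02, with Nppa higher and with Myl7 and Sln at -1.21 and -0.99. Adjusted over the list alone, 3 atrial markers were higher, 1 endothelial marker was higher and 3 lower, and 2 smooth muscle markers were higher and 2 lower. Markers of lung, thymus, T and NK cells, B cells, erythroid cells and nerve had medians between -0.11 and 0.01, where the T and NK cell list had a median just above 0 and a test direction below 0. The lists for glycolysis, endoplasmic reticulum stress, antioxidant defence, apoptosis, the circadian clock and the cell cycle had medians between -0.04 and 0.07.

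No difference between the groups in the spread of their hearts passed the test. The root mean square distance of an array from its group's median profile averaged 0.179 in transgenic and 0.201 in wild-type hearts on the log2 scale (two-sided exact permutation test, p = 0.28, n = 6 each, where 0.0022 is the smallest p possible). None of the 11 list calls held with an estimated correlation. Fry called 3 of them (hypertrophy, sarcomere and adipocyte), as did the exact permutation of list means (hypertrophy, neutrophil and adipocyte). With the slide set as a block, 145 probes and the same 11 lists were called. Within the first and the second set of slides, with 3 arrays per group in each, 33 and 12 probes were called. Myh7 differed by 2.64 and 1.44 within them, Nppa by 2.41 and 1.299, Acta1 by 1.03 and 0.78 and Nppb by 1.26 and 0.04. The medians within the first and second sets were 0.59 and 0.14 for the hypertrophy list, 0.28 and 0.15 for matrix, 0.10 and 0.07 for sarcomere, 0.13 and 0.18 for fibroblast and 0.18 and 0.21 for adipocyte genes. They were -0.20 and 0.02 for fatty acid genes, so that this list's direction did not hold within the second set. They were -0.05 and -0.02 for oxidative phosphorylation, -0.03 and -0.05 for ion channel, -0.25 and -0.52 for immediate early, -0.26 and -0.10 for interferon and -0.26 and -0.82 for neutrophil genes. The hearts that stood apart shared slide sets. Transgenic hearts 4 and 6 and wild-type hearts 1 and 5 lay in the first set, and wild-type hearts 3 and 4 in the second. Contrasts between the sets can therefore not be told apart from these hearts.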

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

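No test in this part was chosen after its result was seen. Over 144 groups of 6 arrays, for the named probes and the gene lists, 5 had a lowest or highest heart far from the rest, where chance gives about 7. Wild-type heart 6 had the highest Nppb of its group, at 14.49 against 13.37 for the next, a gap of 0.769 of the group's range. Transgenic heart 3 had the highest Myo5c, at 7.68 against 7.44, a gap of 0.654. Transgenic heart 4 had the lowest Mybpc2 of the transgenic hearts, at 12.20 against 12.48, a gap of 0.635. Wild-type heart 2 was lowest for the glycolysis list, with a gap of 0.676, and for the tricarboxylic acid cycle list, with a gap of 0.706.

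Other divisions of the same hearts were also compared. The real division called 130 probes, and of 100 divisions of the 12 arrays into 6 and 6, the real one included, only 1 called as many, the real one itself. The highest of the others called 4, so a chance division of the hearts is argued against as the source of the count. Not every possible division was drawn, and mixed divisions hold the group difference within their spread, which can lower their counts. A difference that follows the groups without coming from the transgene would give the same result, and this comparison cannot tell it apart.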

How the results depend on the processing

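The omission of pairs of hearts or of saturated probes and the exact permutation of list means were tests chosen after seeing the data. The 130 called probes, 79 higher and 51 lower, varied with most settings, and no setting turned a called probe it tested. Fewer were called with the subtracted raw intensity (60, of which 34 higher and 26 lower), with an offset of 10 (61, 34 and 27), with the authors' value table (34, 22 and 12), with no filter on dim probes (84, with 48 higher), with a filter at 3 arrays (83, with 47 higher) and without moderation (68, 40 and 28). Median scaling called 33 lower. More were called with a filter at all 12 arrays (251, 132 and 119), with trend and robust variance (226, 127 and 99) and with array weights (419, 256 and 163). A minimum of 1.5-fold left 59 (40 and 19), an adjusted p under 0.01 left 45 (27 and 18), and one under 0.1 gave 418 (232 and 186). Leaving out 1 heart gave 61 to 420 probes, 35 to 200 higher and 26 to 220 lower. The highest count was without wild-type heart 6, and the lowest without wild-type heart 3. Leaving out wild-type hearts 3 and 4 gave 55 (29 and 26) and transgenic hearts 4 and 6 gave 69 (44 and 25), while without wild-type hearts 1 and 5 there were 154. The cause of these moves was not tested, apart from the stricter or looser thresholds. The Pln difference, from saturated spots, was -0.063 to -0.034 with 1 heart left out.

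The replicate number as a block gave 105 probes and changed no list call. Same-numbered hearts did not deviate together, with correlations of -0.169 to 0.083 and 0 of 6 numbers pairing best with each other, so the numbers give no pairing.

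Of 11 lists called, camera with an estimated correlation called 0, fry 3 (hypertrophy, sarcomere and adipocyte), and the exact permutation of list means, 3 (hypertrophy, neutrophil and adipocyte). Under these tests list medians are unchanged by construction: 0.38 for hypertrophy, 0.074 for sarcomere, 0.25 for matrix, 0.13 for fibroblast, 0.16 for adipocyte, -0.12 for fatty acid, -0.040 for oxidative phosphorylation, -0.10 for ion channel, -0.39 for immediate early, -0.090 for interferon and -0.47 for neutrophil genes. The sarcomere call also ended with median scaling (median 0.089), with the authors' table (0.12) and without wild-type hearts 1 and 5 (0.049). The fibroblast call ended with the authors' table (0.079) and without wild-type hearts 3 and 4 (0.11) or transgenic hearts 4 and 6 (0.097). The ion channel call ended with the filter at all 12 arrays (-0.077) and without wild-type hearts 1 and 5 (-0.073), wild-type hearts 3 and 4 (-0.050) or transgenic hearts 4 and 6 (-0.032). The fatty acid call ended without wild-type hearts 1 and 5 (-0.062) and turned to 0.019 without transgenic hearts 4 and 6, which also ended the oxidative phosphorylation call (-0.022). The immediate early call ended without wild-type hearts 3 and 4 (-0.080). Leaving out 1 heart gave 9 to 13 called lists and medians of 0.32 to 0.47 for hypertrophy, 0.057 to 0.10 for sarcomere, 0.17 to 0.32 for matrix, 0.098 to 0.19 for fibroblast, 0.13 to 0.26 for adipocyte, -0.16 to -0.043 for fatty acid, -0.046 to -0.029 for oxidative phosphorylation, -0.14 to -0.050 for ion channel, -0.50 to -0.25 for immediate early, -0.21 to -0.074 for interferon and -0.60 to -0.35 for neutrophil genes. One such omission or more ended the fatty acid, oxidative phosphorylation, ion channel and fibroblast calls. The cause of these changes was not tested. Leaving out probes saturated on all 12 arrays kept all 11 calls. The difference in spread was -0.035 to -0.011 with 1 heart left out, never past the threshold.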

Other observations

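The tests of other probes of the same genes, of chance placement along the chromosome, with its window of 50 genes, and of blood were chosen after the values were seen. So were the genes named in this part, and the omission of wild-type hearts 3 and 4. Ahsg and Fetub, which encode the circulating fetuins and are called genes outside the lists, were higher by 0.71 and 0.69 on the log2 scale, and their chromosome 16 neighbour Masp1, a complement-activating protease, by 0.46, each past the threshold in limma's test. A second Ahsg probe passed at 0.58, others differed by 0.26 and 0.17, and a second Masp1 probe, at 0.51, did not pass. F3, the gene of tissue factor, which starts coagulation, was higher by 0.55. Bambi, a decoy receptor of the TGF-beta family, was higher by 0.64, and Gadd45g by 0.70. Esrrg, a nuclear receptor of mitochondrial gene control, was lower on 1 probe with a difference of -0.46, while others differed by 0.03 and -0.01.

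The 9 probes with the smallest adjusted p were all higher in transgenic hearts, 8 of them by 1.22 to 2.58 on the log2 scale. The other, an unnamed probe, was near background on 4 wild-type arrays, so that the size of its difference depends on the background correction and is not given. For 4 of these genes a rise of the whole gene is argued against, since their 10 other probes had a median difference of 0.076 and none exceeded 0.26. Most of these are dim, and 2 for Scn8a were near background on some arrays, where a rise is hard to see. The 8 above background on all arrays, at least 1 per gene, had a median of 0.06. Other probes of Asnsd1 and Ankrd33b with wild-type values of 10.86 and 10.87 differed by -0.09 and -0.17. Processing is argued against as well, since the lowest difference under 11 processing alternatives was 0.958 and no call was lost. In a test fixed before its result was seen, the 9 probes had a weak mean pairwise correlation over the transgenic hearts, 0.302, above 98.7% of 1000 sets of matched probes, of which the highest had 0.409. The matched sets were of uncalled probes alike only in level, so any change that the 9 probes share would also raise this correlation. The test therefore cannot single out 1 RNA. A transgene transcript, or another RNA present only in transgenic hearts, that several probes capture stays open. So do changes of single isoforms, and probe sequences were not used here.

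Called genes lay close together on chromosome 3, by gene order in GRCm38.p6. A window of 50 neighbouring measured genes held 8 of them, 3 higher (Trmt13, F3 and Palmd) and 5 lower (Lrrc39, Tlcd4, Arhgap29, 1810037I17Rik and Usp53), where 10000 random draws gave at most 6 (permutation p = 1e-04, the smallest these draws can give). For the calls of the main settings, chance placement is thus argued against. So are neighbouring probes that read 1 transcript, since with adjacent called genes counted once the permutation p was 7e-04. Lrrc39 and Palmd passed narrowly, at limma adjusted p-values of 0.0488 and 0.0494, and the groups overlapped for Palmd. Trmt13 is also among the raised probes described above. The result rests in part on these calls, and no other setting was tried for the window. Sequence differences under single probes stay open, because only 1 of 4 other probes, of 3 of these genes, changed the same way at an unadjusted p under 0.05, which is too few to decide. A linked chromosome segment, for example at the site of insertion, may also account for the pattern, and it was not tested.

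Neutrophil and immediate early genes were lower in transgenic hearts in camera's test at its preset correlation. With an estimated correlation neither list was called (adjusted p = 0.27 and 0.52), fry called neither, and no member passed over all probes. The exact permutation of list means, added after seeing the data, called the neutrophil list (adjusted p = 0.036) but not the immediate early list (adjusted p = 0.27). Erythroid markers had a median difference of -0.083, with Epor lowest at -0.18 and Alas2 at -0.15, against the -0.47 of the neutrophil markers. Haemoglobin genes were not among the 6 measured. Within the first set of slides the erythroid and neutrophil medians were -0.18 and -0.26, and within the second 0.05 and -0.82. Blood left in the wild-type hearts is thus argued against within the second set only, and stays open within the first. High values in wild-type hearts 3 and 4 could account for part of the lower neutrophil and immediate early values. Without them the neutrophil median was -0.240 and still called at the preset correlation, while the immediate early list lost its call, so this cannot be told apart for the lists as a whole. A difference in tissue handling between hearts and an effect of the transgene stay open, and neither was tested.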
